A study of Homo sapiens with 2 samples.

How the data were processed

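H3K27me3 ChIP-seq was analysed in 2 libraries of HCT116 cells, which make up 1 group. The deposited files hold raw read counts per bin of 1000 bases, a unit stated in the text deposited with the series, and bins with no read are not listed. Reads were aligned with BWA 0.7.12 to hg19, also named GRCh37, per the submitters' processing notes. The counting tool and the treatment of duplicates and of mapping quality are not given in the sources used here. Even counts were in excess, making up 67.9% of the listed bins with 1 to 10 reads in both libraries, as would arise if mates of a pair were counted one by one.

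Reads were summed in 5 kb bins of chromosomes 1 to 22 and X, and the level of a bin was its read count over the library's autosomal mean across bins with at least 1 read. A bin was enriched when a one-sided Poisson test against that mean gave a Benjamini-Hochberg adjusted p under 0.05 and the level was at least 2-fold, in both libraries. Enriched bins separated by at most 1 bin were merged into domains. The level of a domain is the mean over its enriched bins, without the bins of its gaps. Replicates were compared by correlation of log2(level + 0.1) across bins, by shared bins and domains, and by a binomial test per bin. There was no test between groups, and values are given per library or as mean and SD with n = 2. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

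The total depth was 53187504 and 97031399 reads, in 2470347 and 2652211 listed bins of 1 kb. Intervals for shares of reads are Wilson 95% intervals, and the limit for a count of 0 is 3 counts of the total; both cover counting error only. The procedure was tested on simulated counts for the 28449 bins of chromosome 8: it found 98.7% of bins planted at 2.5-fold, 100% at 3-fold and 0 of those at 1.5-fold, and 176 of 180 domains of at least 3-fold with both ends within 1 bin. The planted domains were uniform blocks of equal length on a flat background of 0.5-fold, with reads drawn in pairs and none planted at 2-fold. Real domains vary in length and level, with a median length of 10 kb, so these recovery rates do not describe the real calls. For the binomial test, libraries were simulated with single independent reads. It found 97 of 100 bins changed 2-fold between them and called 8 of 28249 unchanged ones. These rates do not carry over to the real libraries, where the split of reads varied 2.62 times as much as single reads would. Reads drawn in pairs gave a dispersion of 1.99, and single reads 1.00.

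The tests of enrichment and of the difference between replicates, the bin, the thresholds and the half-width of 3 Mb around MYC were fixed before the data were examined. Chosen afterwards were the centre of that window, the length limits of 50 kb, 100 kb and 2.5 Mb, the limit of 0.5-fold, the tolerance of 0.005 between correlations, the chromosome segments described among the observations, and the tests of explanations, apart from those of domain edges and of the enriched share on X. The plan named random windows of the autosomes; all windows at steps of 1 Mb were used instead. The alternatives tried were other bins, fold minimums, scalings, gaps, overlaps, pseudocounts and window widths, and each replicate left out. Added after the data were seen were counts divided by the dispersion, thinning of replicate 2 and omission of incompletely listed bins. Both fold minimums around MYC and the halved minimum for intervals on X were also added then.

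The gene table used has positions on GRCh38 and served only for which genes neighbour MYC. Gene positions on hg19 were not used here, so the planned promoter levels, gene lists and gene density classes were not run, the rule for named genes was not applied, and no gene is assigned to a domain. Duplicate and mapping-quality filters need single reads and were not run. Reads on chromosome Y are left out.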

Results

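H3K27me3, the trimethylation of lysine 27 on histone H3 that Polycomb repressive complex 2 deposits, was mapped by ChIP-seq in HCT116, an established human colon cancer cell line. The series held 1 group of 2 libraries, described in the labels as biological replicates, and neither an input library nor a second antibody was used here. Replicate 1 held 53187504 reads and replicate 2 held 97031399 reads. Per 5 kb bin, the autosomal mean was 97.8 reads in replicate 1 and 178 reads in replicate 2, so counting error at 2-fold over that mean, widened by the dispersion between the libraries, was 11.6% and 8.58% of the level. All levels below are folds over each library's autosomal mean, and positions are on hg19.

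The first question was how H3K27me3 was distributed over the genome of these cells. Most of the autosomal genome was poor in the mark: 58.3% of 5 kb bins in replicate 1 and 58.6% in replicate 2 lay under 0.5-fold, and the median bin stood at 0.368 and 0.365. A minority of bins carried most of the signal. Autosomal bins at or above 2-fold made up 15.6% of bins in each library and held 60.4% of the autosomal reads in replicate 1 and 60.1% in replicate 2 (Wilson 95% half-widths of 0.0133 and 0.00986 percentage points). In both libraries together 79198 of 562365 bins were enriched, or 396 Mb. Enrichment was called with a one-sided Poisson test per bin, Benjamini-Hochberg adjusted, and at least 2-fold over the mean; at this depth each bin past 2-fold also passed the Poisson test, so the fold minimum alone set the number. The extent therefore followed the threshold: 243 Mb passed at 3-fold, 606 Mb without a fold minimum, and 842 Mb when levels were scaled to the median autosomal bin.

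**Figure D1:**
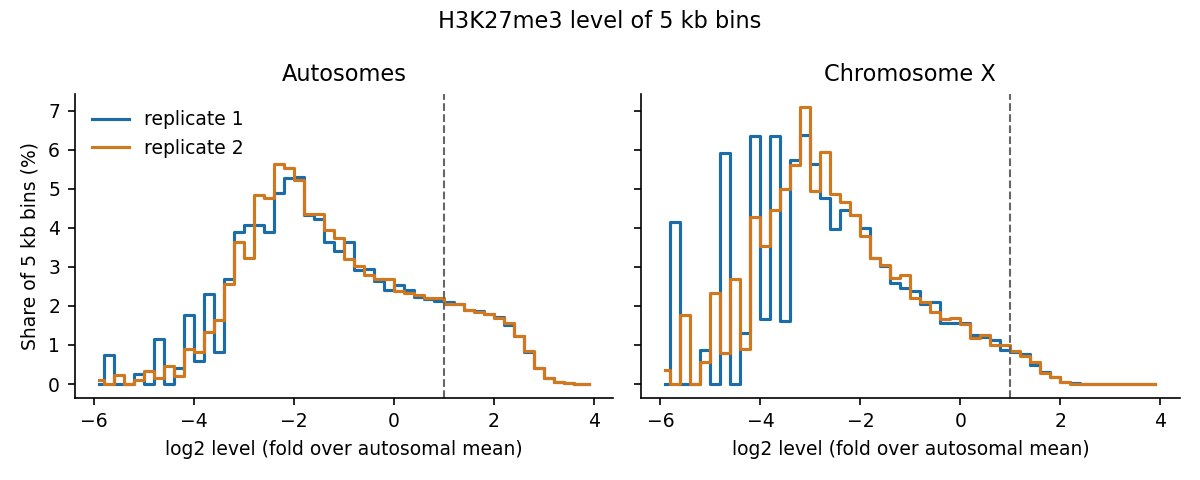
Share of 5 kb bins (vertical axis, percent) by log2 level (horizontal axis, fold over the autosomal mean) on the autosomes and on chromosome X, for bins with at least 1 read; lines are the 2 replicates and the dashed line marks the 2-fold minimum. The autosomal median lies near 0.37-fold in both replicates, and chromosome X lies to the left of the autosomes; the jagged steps at low levels come from bins with few reads.

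The second question was how far the replicates differed. The same regions were enriched in both: 94.1% of the enriched bins of replicate 1 were enriched in replicate 2, and the shared bins made up 89.2% of all bins enriched in either, where 12544 shared bins would arise by chance against the 79198 found. Across bins, which are not independent replicates, Pearson's r of log2 levels was 0.968 and Spearman's rho was 0.934. A binomial test per bin, Benjamini-Hochberg adjusted, called 32120 bins different, 15900 higher in replicate 1 and 16220 higher in replicate 2. That test takes each read as independent, and the split of reads between the libraries varied 2.62 times as much as single reads would. With counts divided by this dispersion the same test called 0 bins, with 18722 bins (3.33%) at an unadjusted p under 0.05. The dispersion was estimated from these same libraries and so absorbs any real difference between them, which leaves the number of differing bins undetermined. The spread between these libraries may be technical and may leave out variation between cultures.

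Enriched bins formed domains of very unequal length. Merging across gaps of at most 1 bin gave 13260 domains over 426 Mb, with a median of 10 kb, and 5085 of them were single bins. The 940 domains of at least 100 kb held 48.8% of the total length, and 47 reached 500 kb. The longest covered 970 kb on chromosome 14, from 22045001 to 23015000, at 5.39 ± 0.0108 (SD, n = 2). The next were 940 kb on chromosome 8 from 96300001 to 97240000 (5.90 ± 0.0449), 835 kb on chromosome 17 from 71365001 to 72200000 (5.49 ± 0.0256), 790 kb on chromosome 10 from 13760001 to 14550000 (4.11 ± 0.0153) and 760 kb on chromosome 12 from 66880001 to 67640000 (4.85 ± 0.00128), each as SD with n = 2. The number of domains depended on how bins were joined, with 19335 when no gap was allowed and 8496 at a gap of 3 bins, and it was 6876 with 10 kb bins, which change the test and the joining together. Without a gap the longest domain was 660 kb. Copy number is not corrected in these lengths and levels, and the domains named on chromosomes 8 and 17 lie in segments with raised levels, described among the observations.

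Longer domains stood higher. In replicate 1 the median level was 2.90 in domains of 10 to 20 kb, 3.60 at 50 to 95 kb, 4.10 from 100 kb to under 250 kb and 4.67 at 250 kb or more, and replicate 2 gave 2.89, 3.59, 4.08 and 4.66. Single-bin domains had the lowest median of the length classes in both libraries, which a threshold on single bins favours. Length and level both come from the same 2-fold cut on the same bins, so the rise of level with length is not an independent result. Among domains of at least 50 kb, the highest level was 11.4 ± 0.0711 on chromosome 1 from 144980001 to 145130000. It was followed by 9.01 ± 0.0358 on chromosome 17 from 46205001 to 46615000 and 8.36 ± 0.0971 on chromosome 16 from 82045001 to 82160000 (SD, n = 2). With no input library, this ranking is not corrected for copy number or mappability. The domain on chromosome 17 lies beyond 45 Mb, where the 99th percentile of levels was 1.62 times that of the autosomes outside the segments with raised levels. Of the domains found in replicate 1, 91.4% overlapped a domain of replicate 2 by at least 1 base, and 81.9% did so over 50% of each. The limits of 50 kb and 100 kb were chosen after the lengths had been seen.

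At the edges of domains of at least 100 kb the level fell, also when read in the library that did not set the edge. With edges taken from replicate 1 and levels from replicate 2, the mean level was 3.56 at 10 kb inside the edge and 1.37 at 10 kb outside, and it passed from 2.43 to 1.88 between the first kb inside and the first kb outside. Edges from replicate 2 with levels from replicate 1 gave 3.55 and 1.34. An edge is by construction followed by at least 2 bins of 5 kb under the threshold in the library that sets it. The point 10 kb outside lies within those bins. The fall is thus in part fixed by the rule, and how steep it is cannot be taken as an independent result. Farther out, at 30 kb, the level was again 2.14 and 2.11, since the rule does not reach there and other domains lie nearby.

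**Figure D2:**
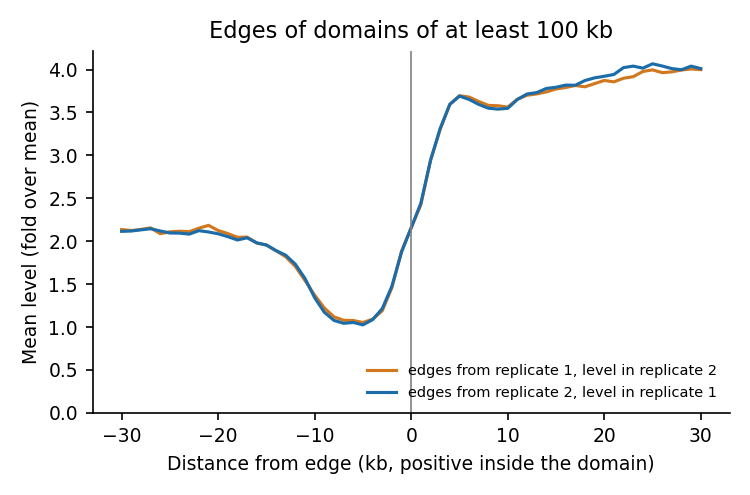
Mean H3K27me3 level (vertical axis, fold over the autosomal mean) by distance from the edges of domains of at least 100 kb (horizontal axis, kb, positive inside), with edges from one replicate and levels from the other. The level falls from 3.56 at 10 kb inside to 1.37 at 10 kb outside for edges from replicate 1.

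The title of the series names MYC, the oncogene transcription factor gene on chromosome 8, and its enhancers, so the mark was described in the 6 Mb around it. In the GRCh38 gene table MYC lies between the long noncoding RNA genes CASC11 and PVT1, with POU5F1B, CCAT2, CASC8, CASC21 and CCAT1 beyond CASC11 and CCDC26, GSDMC and CYRIB beyond PVT1. On hg19 the window from 126 to 132 Mb was centred on the whole Mb nearest to MYC, a position taken from general knowledge, since the files hold no gene positions. The window had a mean level of 0.810 in replicate 1 and 0.819 in replicate 2, against 1.34 over chromosome 8 in both. Its median bin stood at 0.511 and 0.522, above the autosomal median bin of 0.368 and 0.365. In both libraries together 63 of its 1200 bins (5.25%) were enriched, against 20.6% of chromosome 8. Of these enriched bins 55 lay in the last Mb, from 131 to 132 Mb, where a domain crosses the end of the window. The mean, the share and the ranks of the window therefore depend on where it ends. Among 2509 autosomal windows of 6 Mb the mean level ranked at percentile 39.6 and the share of enriched bins at percentile 26.6. These levels, shares and ranks are not corrected for copy number: the window lies in the part of chromosome 8 beyond 70 Mb. There, over bins with every 1 kb bin listed, the 10th percentile of levels was 1.48 times that of the autosomes outside the segments with raised levels. The 99th percentile was 1.40 times theirs.

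The central 2 Mb, from 128 to 130 Mb, had a mean level of 0.531 in each library and 0 of 400 bins enriched in both. Its median bin stood at 0.501 in replicate 1 and 0.517 in replicate 2, also above the autosomal median bin. The mean level ranked at percentile 32.7 among autosomal windows of 2 Mb. Replicate 1 alone had 1 enriched bin. The limit for a count of 0, here a share of 0.75%, would hold for independent bins. These are all the bins of the stretch, and neighbours depend on each other. An absence of bins enriched in both libraries was common, as 19.5% of 2607 autosomal windows of 2 Mb also had none. No bin enriched in both libraries lay between 127670001 and 130845000, a stretch of 3.175 Mb. The domains of at least 100 kb on either side were 6.56 Mb apart, from 125200001 to 131760000, and the distal one, from 131760001 to 132070000, reached 5.82 ± 0.0344 (SD, n = 2). Of the window, 9.25% was enriched without a fold minimum, and the centre was set after levels on this arm had been viewed.

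**Figure D3:**
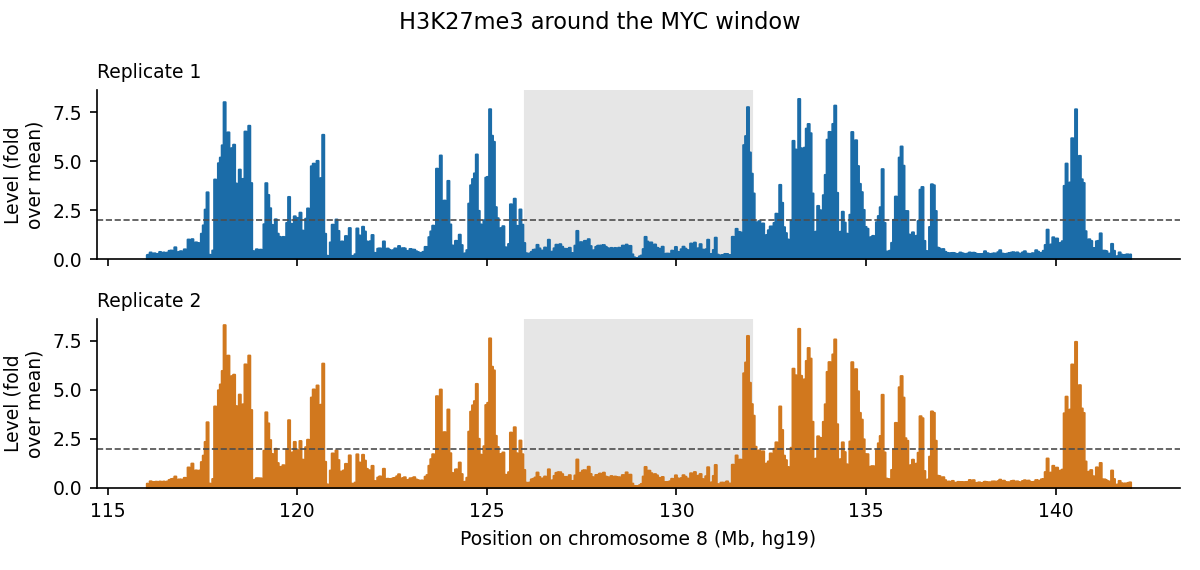
H3K27me3 level in 50 kb means (vertical axis, fold over the autosomal mean) along chromosome 8 (horizontal axis, Mb on hg19) in each replicate; the grey band is the window from 126 to 132 Mb and the dashed line the 2-fold minimum. The 50 kb means in the band stay under the 2-fold line up to the domain that starts at 131760001, although shorter domains were called there.

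The chromosomes differed by more than the replicates did. Chromosome 20 had the highest mean level, 1.40 ± 0.000239, followed by chromosome 17 at 1.35 ± 0.00469 and chromosome 8 at 1.34 ± 0.00479. Chromosome 4 was the lowest autosome at 0.567 ± 0.00373, and chromosome X stood at 0.348 ± 0.00205 (each SD, n = 2). The share of bins enriched in both libraries was highest on chromosome 20, and it was 20.1% on chromosome 17, 20.6% on chromosome 8, 5.95% on chromosome 4 and 2.29% on chromosome X. With no input library, copy number and mappability are not corrected in these values.

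**Figure D4:**
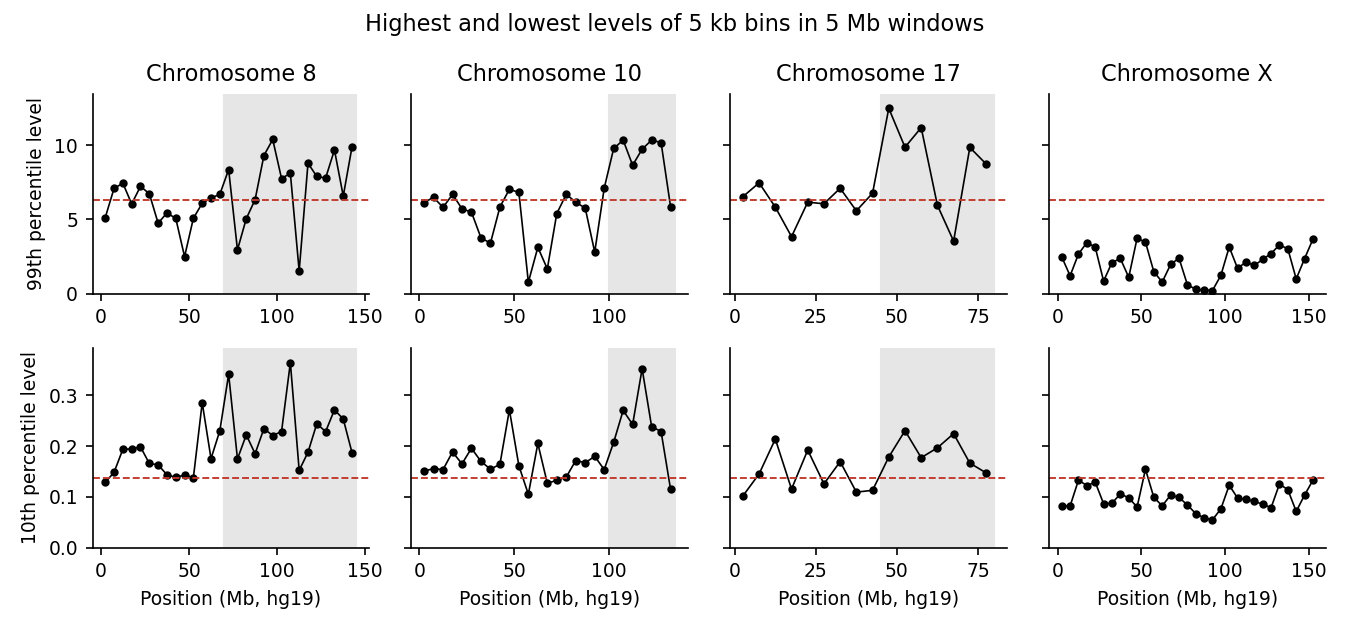
The 99th percentile (upper panels) and the 10th percentile (lower panels) of the mean level of both replicates over 5 kb bins (vertical axes, fold over the autosomal mean) in 5 Mb windows along chromosomes 8, 10, 17 and X (horizontal axes, Mb on hg19). All values are over completely listed bins, those with every 1 kb bin listed. Grey bands mark the distal segments from 70, 100 and 45 Mb, chosen after such windows had been viewed, where the 99th percentile over the whole segment was 8.78, 9.87 and 10.2. Dashed lines mark the autosomes outside these segments, at 6.28 and 0.138.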

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

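The reads described here lie outside the main measurement and exceed the limit that a count of 0 allows, which is 3 reads per library. The mitochondrial genome held 6735 reads in replicate 1 and 9268 in replicate 2. The PhiX contig, a phage genome used as a sequencing control, held 42731 and 44613 reads, or 0.0803% of all reads (Wilson 95% interval 0.0796 to 0.0811) and 0.0460% (0.0456 to 0.0464). The Escherichia coli contig held 456 and 819 reads. Unplaced human contigs held 230877 and 425299 reads, of which the contig GL000220.1 alone held 138416 and 256703.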

How the results depend on the processing

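Counts, the enriched extent and the enriched share around MYC were taken as the same within 1.5 times, lengths and levels within 1 SD of the replicates, shares in common within their Wilson interval, correlations within 0.005 and the longest interval on X within 1 bin; by this, 23 alternatives left a result the same and 36 moved it. Settings added after the data were seen were the dispersion, thinning, complete listing of bins, both fold minimums around MYC and the halved minimum on X. The enriched extent of 396 Mb became 243 Mb at 3-fold, 606 Mb without a fold minimum and 842 Mb when scaled to the autosomal median. The 13260 domains became 19335 without a gap, within 1.5 times, 8496 with a gap of 3 bins and 6876 with 10 kb bins, a setting that changes the bin of the test and the gap together. Their total of 426 Mb became 396, 483 and 438 Mb in those settings, 425 Mb with thinning, and 451 to 453 Mb with a replicate left out; the longest, 970 kb, became 660 kb without a gap, 1100 kb in the other 2 settings, and 970 to 985 kb with a replicate left out. Pearson's r of 0.968 became 0.867 with 1 kb bins, 0.983 with 10 kb bins and 0.986 with a pseudocount of 1, and Spearman's rho of 0.934 became 0.806 and 0.962 with 1 kb and 10 kb bins. Enriched bins in common, 89.2%, became 77.9% and 91.8% with those bins and 88.6% with thinning, and domains in common, 91.4%, became 81.9% when 50% of each had to overlap. The 32120 bins differing between replicates became 0 with counts divided by the dispersion, which absorbs real differences too. The MYC window level of 0.814 became 0.531 in the window of 1 Mb either side, 0.607 scaled to chromosome 8 and 0.785 with completely listed bins. Its enriched share of 5.25% became 0 in the smaller window and 9.25% without a fold minimum. Without the top 0.1% of bins the level became 1.41 on chromosome 20, 0.352 on X, 0.574 on chromosome 4 and 1.32 on chromosome 8. The causes of these moves were not tested. Promoter, gene-list, gene-density, duplicate, mapping-quality and region-score alternatives were not run. No paired analysis was possible because there is 1 group.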

Other observations

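Large parts of the genome held no H3K27me3 domain at the 2-fold minimum, which was applied alike to the autosomes and X. There were 148 domain-free intervals of at least 2.5 Mb in which at least 90% of bins were listed, 837 Mb in total, and 60 of them reached 5 Mb. A 5 kb bin counted as listed with any read in either library, so this share does not measure mappability, which is not corrected here. The longest ran over 28.5 Mb of chromosome X, from 71295001 to 99840000, at a level of 0.134 in replicate 1 and 0.137 in replicate 2. Its 5 Mb windows from 75, 80, 85 and 90 Mb held only 668, 504, 368 and 360 completely listed bins. Windows from 75, 80 and 85 Mb on chromosome 12, also free of domains, held 895, 866 and 874. The next were 21.1 Mb of chromosome 12 from 72365001 to 93425000, at 0.240 and 0.244, and 17 Mb of chromosome 4 from 122720001 to 139720000, at 0.203 and 0.206. Chromosome 4 held 20 such intervals, chromosome 2 held 14 and chromosome X held 12. With the minimum on X halved, a setting added after the data were seen, X held 11 and its longest interval was 23 Mb, from 76760001 to 99740000, with no longer one on the autosomes at the full minimum.

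Beside MYC, the longest run of bins under 0.5-fold in both libraries covered 315 kb from 128805001 to 129120000, at 0.143 and 0.144. Runs of that length were common, with 535 on the autosomes at least as long. At domain edges, the level 10 kb inside over that 10 kb outside, read in the library that did not set the edge, was 2.60 at the lower of both directions. The bound written beforehand for edges set by counting noise was under 1.5, and such edges were not simulated.

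In the weighing that follows, the tests of the chromosome segments, of the level on X and of the noise between libraries were chosen after the values had been seen, and the test of the share on X was written before, except its repeat over completely listed bins. The segments were picked, with their starts, after 5 Mb windows of chromosomes 1, 5, 8, 10, 16, 17, 18 and X had been viewed, together with general knowledge of gains in the HCT116 karyotype. Windows starting at 145 Mb on chromosome 1 and at 20, 80 and 85 Mb on chromosome 16 also had high 99th percentiles, of 15, 9.02, 9.83 and 9.85, and were not among the segments.

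The highest levels were raised on distal chromosomes 8 (from 70 Mb), 10 (from 100 Mb) and 17 (from 45 Mb). There the 99th percentile of completely listed bins was 1.40, 1.57 and 1.62 times that of the autosomes outside these segments. That reference includes the rest of chromosomes 8, 10 and 17. Extra copies may contribute, since the 10th percentile was raised too, by at least 1.29 times. Collapsed repeats in a few bins were tested in 3 ways, each chosen after the one before. The ratio of the median enriched bin, 1.15 at its lowest, lay between its limits of 1.1 and 1.2. At least 10 raised bins in 12 of 16, 6 of 8 and 5 of 8 windows of 5 Mb decided nothing by number alone, as 27.5% of windows on the other autosomes held as many. The shares of such windows ranked at percentile 95.3 or above among stretches of the same length, but the segments had been picked for their levels. Without the 2 windows richest in raised bins the 99th percentile was still at least 1.29 times that of the autosomes outside the segments. It was also above that of every complete stretch of the same length on autosomes other than 8, 10 and 17. The raised levels were thus not confined to 2 windows of a segment. Segments picked for their high windows would tend to pass such a comparison, so it cannot decide on collapsed repeats. More mark per copy with no change in copy number is not excluded by these levels alone. General knowledge of karyotype gains, by which the segments were partly picked, goes against it, but copy number was not measured here. The 10th percentile ranked at 99.4 or above among stretches of the same length. It ranked at 97.9 or above after a linear fit on the share of enriched bins, with which it rose (r across overlapping stretches, 0.464 to 0.518). That fit ran beyond the other stretches for chromosomes 8 and 10, and a gain of mark outside domains would raise the 10th percentile too.

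Chromosome X was low in level and in enriched share. A single copy could account for the highest levels, as the 99th percentile on X, over 21418 completely listed bins, was 0.449 times that of the autosomes outside the raised segments. Other measures over such bins gave other ratios: 0.640 for the 10th percentile and 0.738 for the median enriched bin, which the shared 2-fold minimum keeps from falling far. The 10th percentile there leaves out incompletely listed bins. Over all bins the median level on X was 0.153 in replicate 1 and 0.157 in replicate 2, against 0.368 and 0.365 on the autosomes. The mean level on X was 0.348. With the threshold on X halved, 7.71% of all 29677 X bins passed. Of autosomal bins 14.7% passed at the full threshold, a ratio of 0.523. Over completely listed bins it was 10.6% against 16%, a ratio of 0.662, barely under the bound of 2/3 set beforehand. That repeat leaves out bins with few reads, which are more common on X, and so leans towards a higher share there. Both ratios lay under the bound, which argues against a single copy as the whole account of the share. Fewer domains and lower mappability on X cannot be told apart either.

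In 5 kb bins the libraries differed by a nearly constant multiple of counting noise. Mates or duplicates counted one by one may be a source of part of it, since the dispersion in 5 kb bins was 2.62, but simulated pairs gave 1.99, so pairs alone leave the rest unaccounted for. Large variation between cultures in proportion to the level is argued against in 5 kb bins. There the dispersion in the 20% of bins with the most reads was only 1.06 times that in the 20% with the fewest. Small proportional variation could be hidden by the counting noise of such bins, so this ratio cannot exclude it. In 1 Mb bins the dispersion was 3.73, so smaller differences over long stretches stay open.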
